A study of Arabidopsis thaliana with 22 samples.

How the data were processed

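RNA-seq libraries from Arabidopsis thaliana were examined in 8 groups. Leaves of 3-week-old plants came from the wild type and from a line overexpressing AITF1 (OXAITF1), with 2 libraries per group. Seedlings aged 10 days came from the wild type and from the aitf1-1 asr3-1 double mutant at 0, 1 and 3 h, with 3 libraries per group, so that 22 libraries entered in all. Groups and replicate numbers were taken from the labels. The labels do not name what was applied at 0 h, and no untreated libraries at 1 or 3 h were among those analysed. The growth protocol speaks of 14-day-old seedlings while the sample labels give 10 days, and the extraction text speaks of leaves for every sample. The labels do not say that replicates are separate cultures or plants, so every p-value measures the spread between these libraries, which may be technical.

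The deposited values were whole-number read counts per gene and library, not normalized, in one file per library and again in one table per tissue. Per the submitters' processing notes, HISAT2 2.1.0 and featureCounts from Subread 1.6.5 were used with the TAIR10 genome. The role of each setting, the annotation release, the strand setting and the handling of reads that match several places are not given in the sources used here. Counts of near-identical genes (light-harvesting chlorophyll a/b genes, indole glucosinolate methyltransferases, PP2-B13 and PP2-B14, glutathione transferases, heat shock proteins, cysteine-rich receptor kinases) and of overlapping or antisense genes are therefore uncertain. The leaf files list 23318 genes, with 0 of them at a count of 0 in every leaf library, and the seedling files list 33318 genes, of which 7371 are at 0 in every seedling library. The leaf files hold 117 chloroplast and 94 mitochondrial genes and the seedling files hold 0 organelle genes, so leaf and seedling values were never compared directly. Genes called in one tissue were followed as sets within the other. Gene symbols and coordinates come from the TAIR10.1 reference annotation, which matched 23057 leaf and 32830 seedling identifiers.

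Leaf libraries held 15.3 to 19.4 M counts and seedling libraries 17.1 to 21.6 M. A single count was worth 0.0516 to 0.0654 CPM (counts scaled by the library total, here before TMM factors) in leaf libraries. For a gene with 0 counts in a group, the floor was 3 counts over the whole group, and the fold is then a lower bound that covers counting error only. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 6.76 to 26.1 for replicate pairs in seedlings, 11.5 in wild-type leaves and 72.3 in OXAITF1 leaves, so that no library was a copy of a replicate in its group.

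Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, jsonlite 2.0.0). Low-count genes were removed with filterByExpr, library sizes were scaled with TMM factors, and glmQLFit with glmQLFTest gave two-sided p-values, adjusted by Benjamini and Hochberg within each comparison. A gene was called at an adjusted p under 0.05. The 4 leaf libraries were fitted alone, with 2 residual degrees of freedom, and the 18 seedling libraries were fitted together, with 12. The main fits hold no term for the replicate number. After group means were removed, 13 of 18 seedling libraries correlated best with a library of their own number in another group. Median r was 0.073 for pairs of the same number and -0.049 for other pairs. In leaves 0 of 4 libraries did so. With 2 libraries per group, however, the leaf correlations are 1 value with either sign (r of -0.087 or 0.087). The leaf count therefore cannot decide whether leaf libraries are paired. A replicate block was fitted only as an alternative. The 10 comparisons were OXAITF1 against wild-type leaves, the double mutant against the wild type at each of 3 times, 1 and 3 h against 0 h within each genotype, and the genotype by time interaction at 1 and 3 h. Standard errors of log2 fold changes were derived from the edgeR F statistics. CPM values are TMM-scaled and are given as mean ± SD.

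Gene lists were written before the data were examined, 25 in all, including the WRKY family taken from the reference symbols. In each comparison 23 lists had enough tested genes. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks only whether the list's own members change. Members called were counted with adjustment over all genes and adjusted over the list alone. The genes named in the text follow a rule fixed before the data were examined: ASR3 and AITF1 (where the reference names its locus, which it does not) in every comparison; the 6 highest and 6 lowest called genes of each comparison with a reference symbol, a mean of at least 1 CPM and no overlap between the groups; up to 3 called members of each list with the smallest adjusted p; and trihelix genes called in leaves. Overlaps of called genes were tested with Fisher's exact test (two-sided, 32 tests in the family). The family pools overlaps of leaf with mutant calls and overlaps among seedling comparisons. The latter have far smaller p, which makes the adjustment more lenient for the former.

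Alternatives listed before the data were examined were DESeq2 1.42.0, median-ratio (RLE) size factors, library totals alone, no low-count filter, a stricter filter (at least 1 CPM in every library of a compared group), a 2-fold threshold added to the adjusted p, removal of organelle genes, a replicate block, leaving out each library in turn, the table per tissue as the source of counts, a fit on the compared libraries only, and other set tests. A genotype effect averaged over the 3 times, the overlap of calls without AT3G11100, and the leaf sets without each seedling or OXAITF1 library, were added after the data were seen. Without a leaf wild-type library edgeR called no leaf genes, so there was no set to follow. The method was tested on simulated counts drawn from the real means and dispersions, with 200 genes changed in each of 5 simulations. The changed genes were picked only from those above a minimum mean count. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the gene lists, the sequence word test and the figures. No library was left out.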

Results

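To examine how a pair of trihelix transcription factors, a plant family of DNA-binding proteins named for its helical domain, affects defence gene expression in Arabidopsis thaliana, read counts per gene were analysed for 22 libraries. Leaves of 3-week-old plants were represented by 2 wild-type libraries and 2 libraries of a line overexpressing AITF1 (OXAITF1). Seedlings aged 10 days were represented by the wild type and the aitf1-1 asr3-1 double mutant at 0, 1 and 3 h, with 3 libraries per genotype and time. The treatment that starts at 0 h is not named in the labels. Total counts were 15.3 to 16.6 M in wild-type leaves, 17.3 to 19.4 M in OXAITF1 leaves and 17.1 to 21.6 M in seedlings.

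The targeted genes were examined first. The reference does not name an AITF1 locus, but 1 trihelix gene stood apart in OXAITF1 leaves. AT3G11100 (chromosome 3, 3476187 to 3477900) rose from 14.4 ± 0.0063 CPM in the wild type to 3396 ± 626 CPM in OXAITF1 (SD, n = 2), a log2 fold change of 7.88 (SE 0.31, edgeR adjusted p = 0.0141). In seedlings, AT3G11100 was lower in the double mutant at every time, at 41.2 ± 2.35 against 70.2 ± 0.254 CPM at 0 h, 26.8 ± 2.97 against 48.9 ± 3.46 CPM at 1 h and 35.2 ± 2.32 against 64.1 ± 3.18 CPM at 3 h (SD, n = 3). The log2 fold changes were -0.77, -0.87 and -0.87 (adjusted p = 7.7e-05, 2.4e-05 and 1.7e-05). ASR3 (AT2G33550, chromosome 2, 14209982 to 14211693), a repressor of pattern-triggered immune genes, was also lower in the double mutant. At 0 h it was at 7.32 ± 0.784 CPM in the mutant and 12.0 ± 0.841 CPM in the wild type, and at 3 h at 6.92 ± 0.714 and 12.9 ± 0.796 CPM (SD, n = 3). At 1 h the 3 mutant libraries lay between 5.76 and 7.96 CPM and the wild-type libraries averaged 10.8 ± 0.993 CPM. It fell by 0.71, 0.65 and 0.90 on the log2 scale (adjusted p = 0.0172, 0.0490 and 0.00224). Transcripts of both genes were detected in the mutant. The ASR3 difference kept its size without any 1 library, at -0.78 to -0.62 at 0 h and -0.76 to -0.53 at 1 h, while its adjusted p did not stay under 0.05. At 0 h the adjusted p was 0.118 without wild-type replicate 1, 0.0728 without wild-type replicate 3, 0.0668 without mutant replicate 1, 0.143 without mutant replicate 3, 0.0715 with library totals alone and 0.194 with the compared libraries only. At 1 h it was 0.293, 0.0614 and 0.206 without wild-type replicates 1, 2 and 3, and 0.209 and 0.257 without mutant replicates 2 and 3. It was also 0.0511 with RLE size factors, 0.0582 without a filter, 0.0552 with a stricter filter, 0.0876 with a replicate block, 0.139 with library totals alone and 0.557 with the compared libraries only. In leaves, ASR3 was at 10.7 ± 4.46 CPM in the wild type and 7.40 ± 0.454 CPM in OXAITF1 (SD, n = 2), a log2 difference of -0.53 that did not pass the test (adjusted p = 0.303) and was -0.91 without wild-type replicate 1, -0.032 without wild-type replicate 2 and -0.11 with library totals alone. The AT3G11100 call in leaves was lost without wild-type replicate 1 or 2 (adjusted p = 0.164 and 0.169) and with a replicate block (adjusted p = 0.0527), at log2 fold changes of 7.87 in all 3 fits.

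**Figure D1:**
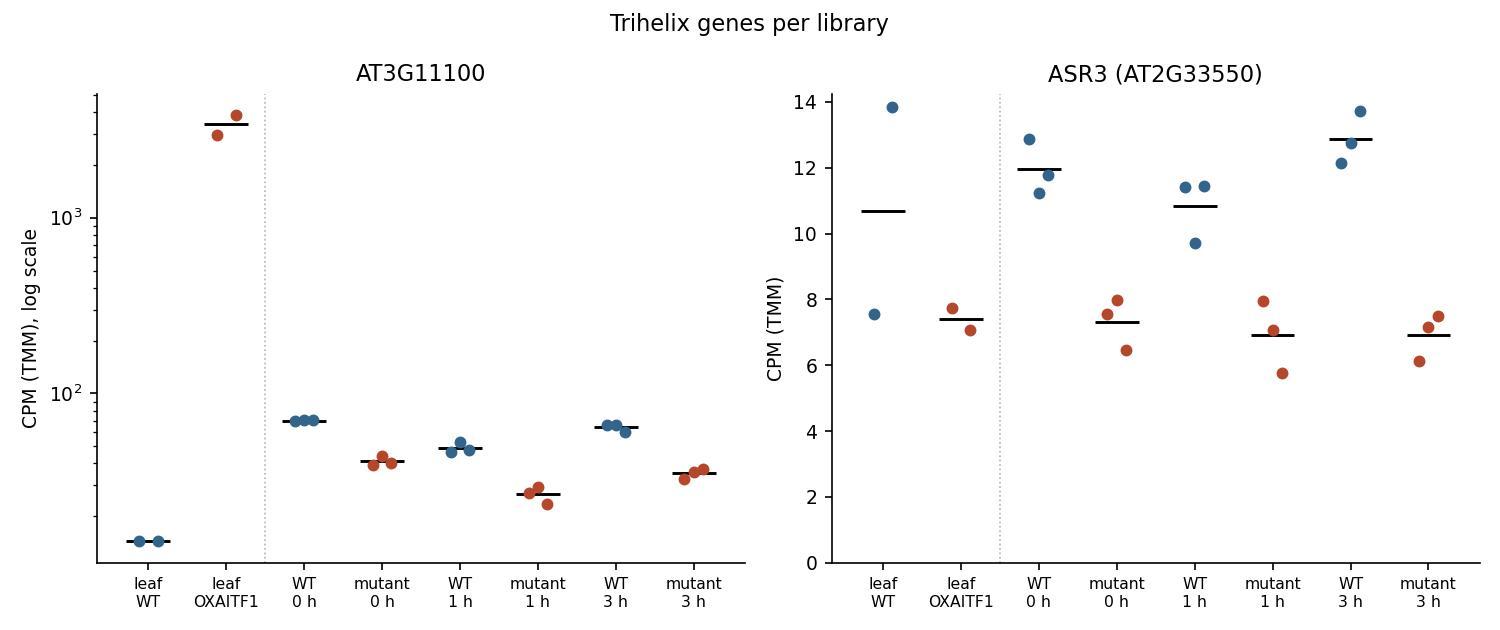
Expression of AT3G11100 (left, log axis) and ASR3 (right) in TMM-scaled CPM on the vertical axis, with 1 point per library, a bar at each group mean, and a dotted line between leaf and seedling groups; blue is wild type and red is OXAITF1 or the double mutant. AT3G11100 averages 3396 CPM in OXAITF1 leaves against 14.4 CPM in the wild type, and 41.2 against 70.2 CPM in mutant and wild-type seedlings at 0 h.

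Among the gene lists, those for photosynthesis, aliphatic glucosinolates and salicylic acid had the smallest adjusted p by limma's camera in OXAITF1 leaves, and each had an adjusted p of 0.180 with an estimated correlation, where no list call held. Among genes for light harvesting and carbon fixation, 24 of 28 tested members fell, with a median log2 fold change of -1.57. LHCB2.3, a light-harvesting chlorophyll a/b protein, went from 2134 ± 223 to 185 ± 72.8 CPM (SD, n = 2), and RBCS2B and RBCS1B, small subunits of Rubisco, fell by 2.19 and 2.70 on the log2 scale (SE 0.21 and 0.23). Of the genes for aliphatic glucosinolates, the methionine-derived defence compounds, 15 of 18 fell, with a median of -3.49. CYP79F1, which carries out the first step of the core pathway, went from 385 ± 33.9 to 10.6 ± 5.20 CPM, and BAT5, which moves chain-elongation intermediates into plastids, from 60.1 ± 1.82 to 2.92 ± 0.354 CPM (SD, n = 2).

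Genes of salicylic acid metabolism and systemic acquired resistance went the other way: 14 of 26 rose, with a median of 1.68 (2.62 without wild-type replicate 1). DMR6 and DLO1, enzymes that hydroxylate salicylic acid, rose by 2.87 and 4.47 on the log2 scale (SE 0.18 and 0.32), DMR6 from 25.5 ± 0.694 to 186 ± 25.9 CPM (SD, n = 2), and PNP-A, a secreted peptide, rose 13.1-fold. By camera the adjusted p was 3.3e-14 for photosynthesis, 8.9e-11 for aliphatic glucosinolates and 7.7e-08 for the salicylic acid list (0.180 for each with an estimated correlation). Adjusted over the list alone, 25, 18 and 17 members were called. Of the 23 lists tested in leaves, fry called 8. The 10 most abundant genes took 13.7% of counts in the wild type and 8.98% in OXAITF1.

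Smaller groups moved in part. Of the ethylene genes 5 of 17 rose, among them the receptor ERS2 (log2 fold change 1.62, SE 0.21) and EBF2, an F-box protein that removes the regulator EIN3 (1.04, SE 0.17), with a camera adjusted p of 0.0405 and an adjusted p of 0.757 with an estimated correlation; 8 were called adjusted over the list alone. Of 48 WRKY transcription factors 10 rose, led by WRKY4, WRKY50 and WRKY38 (1.07, 2.59 and 3.03), and 1 fell (adjusted p = 0.0496, and 0.482 with an estimated correlation; 16 higher and 1 lower adjusted over the list alone). Among 8 guard cell markers, ALMT12, an anion channel, went from 10.2 ± 2.02 to 3.38 ± 1.47 CPM (list adjusted p = 0.0405 and 0.482 with an estimated correlation; 4 adjusted over the list alone). The ethylene and guard cell calls were lost without wild-type replicate 1 (adjusted p = 0.0575 for both lists), and the ethylene, guard cell and WRKY calls without OXAITF1 replicate 2 (adjusted p = 0.266, 0.0751 and 0.0890). With library totals alone the adjusted p was 0.0607 for ethylene, 0.337 for WRKY and 0.0780 for ALMT12, and with a stricter filter 0.0945 for ethylene and 0.107 for WRKY. It was 0.0513 for WRKY without organelle genes and 0.0977 for guard cells by DESeq2. Of the cysteine-rich receptor kinases 8 of 23 rose and 3 fell, with CRK6 and ARCK1 at 2.40 and 2.35 and CRK21 at -3.42 (list adjusted p = 0.0696).

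The remaining lists did not pass the list test in leaves. Among 31 early pattern-triggered genes, 6 rose and 1 fell. FRK1, a receptor kinase used as a marker of flagellin responses, averaged 0.0374 CPM in the wild type and 5.15 CPM in OXAITF1, while WRKY11 fell by 1.68 (list adjusted p = 0.456). The jasmonate list had 5 higher and 5 lower members of 34, with the transcription factor NAC019 at 2.87, the repressor JAZ1 at -1.68 and the biosynthetic enzyme AOC2 at -1.86. In the camalexin and indole glucosinolate list, 2 of 22 rose and 3 fell, with PAD3, the last enzyme of camalexin synthesis, at 3.41 and the glucosinolate enzymes UGT74B1 and SUR1 at -1.49 and -1.44. Single members rose among pattern receptors (RLP23, 1.89), intracellular immune receptors (NRG1.2, 1.01), clock genes (BOA, 3.07) and phloem and trichome markers (GL2, 2.21). Of 23 abscisic acid, drought and cold genes 3 rose and 2 fell (HAI1 at 5.74, NCED3 at -1.36). The auxin list had 4 higher and 2 lower of 14 (WES1 at 3.55), heat shock 2 higher of 8 (HSFA2 at 3.13), and the trihelix family 5 higher of 22, with GT2L, AT3G10030, AT2G44730 and GT-1 at 1.37, 1.01, 0.81 and 0.79 beside AT3G11100 (GT-1 had an adjusted p of 0.0511 with RLE size factors). No edgeR call was made among 11 touch, 7 flavonoid, 7 cell cycle, 2 root and 6 reference genes. Several of the strongest single changes were genes with 0 counts in both wild-type libraries, which gives lower bounds against a floor of 3 counts over the group. THA1, a threonine aldolase, was at least 222-fold higher, the transporter UMAMIT33 at least 165-fold and the alternative oxidase AOX1D at least 68.7-fold. The lowest called genes were XTH31, a cell wall xyloglucan enzyme (log2 fold change -5.91, SE 0.74), and the esterase MES18 (-5.69, SE 0.89).

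Over all 18639 genes tested in leaves, edgeR called 3692 (1745 higher, 1947 lower), of which 2574 changed at least 2-fold, and DESeq2 called 4491, with 3517 shared. With library totals alone the count was 6414 (5287 higher, 1127 lower) and the median over all genes moved from 0.05 to 0.46, so directions of small changes in leaves depend on the scaling. With 2 libraries per group the calls were fragile: without wild-type replicate 1 or 2, which leaves a lone library assumed to vary like the other group, edgeR called 0 genes (4033 and 3990 at an unadjusted p under 0.05, and 1119 and 1050 by DESeq2). With a replicate block edgeR also called 0 (6060 at an unadjusted p under 0.05, lowest adjusted p 0.0527, and 4491 by DESeq2 without a block), so every call of a single leaf gene named here is lost with it, while camera called 6 lists. Without OXAITF1 replicate 1 or 2, the lone OXAITF1 library is likewise assumed to vary like the wild type. OXAITF1 replicates differed more than wild-type replicates (chi-square per degree of freedom 72.3 and 11.5). Those fits drop the larger spread, so their higher counts do not show that the calls are stable. In simulated leaf counts 59.4% of 4-fold changes, 1.79% of 2-fold changes and 0.299% of log2 changes of 0.5 were recovered, and 19.1% of calls were false. Each simulation changed 200 genes, far fewer than the 3692 called here. Recovery and the share of false calls depend on how many genes change, so these values need not carry over to the real leaves.

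**Figure D2:**
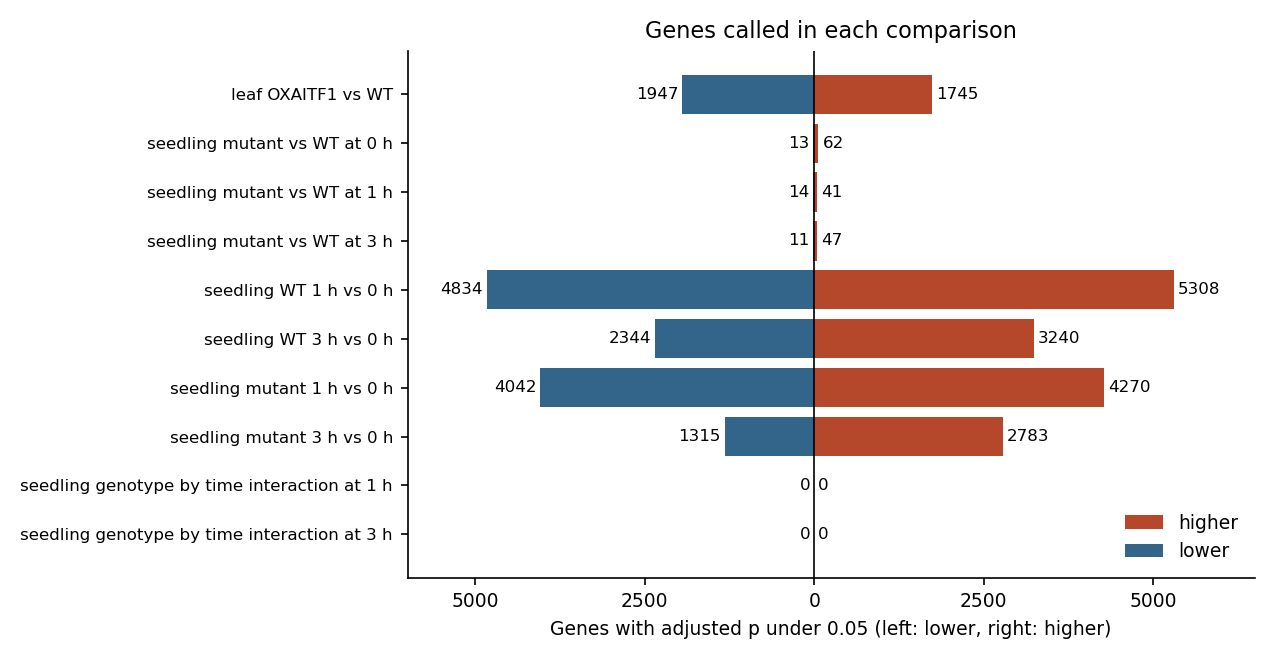
Number of genes with an edgeR adjusted p under 0.05 in each of the 10 comparisons, with higher genes drawn in red to the right and lower genes in blue to the left. Counts range from 5308 higher and 4834 lower genes in wild-type seedlings at 1 h to 0 for both interactions.

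To find genes that depend on the pair of factors in seedlings, the double mutant was compared with the wild type at each time. Few genes changed. ECT4, a reader of methylated adenosine in RNA, rose from 25.9 ± 1.36 to 68.2 ± 1.69 CPM at 0 h (SD, n = 3), with log2 fold changes of 1.17 and 1.21 at 1 and 3 h (SE 0.09). The ubiquitin protease UBP20 rose by 1.42, 1.07 and 1.21 (SE 0.08), and MSH5, a meiotic recombination protein, by 1.51, 1.62 and 1.59 (SE 0.20 to 0.21). The endosomal sodium/proton antiporter NHX6 rose by 1.06, 0.89 and 0.76, the phosphoinositide phosphatase SAC8 by 0.92, 1.03 and 1.01 and the histone deacetylase HDT4 by 1.05, 1.04 and 1.03 at 0, 1 and 3 h. The anaphase-promoting complex subunit APC11 rose by 1.08 at 0 h and was not called at 1 or 3 h (0.55 and 0.69). FHIT, a nucleotide hydrolase, fell by 0.87, 0.88 and 0.76, and PIR121, a subunit of the actin-regulating WAVE complex, by 0.53, 0.59 and 0.55. With the compared libraries only, the adjusted p was 0.0839 for APC11 and 0.140 for PIR121 at 0 h. It was 0.0524 for MSH5, 0.0549 for PIR121 and 0.0992 for FHIT at 1 h, and 0.0846 for HDT4, 0.0604 for PIR121 and 0.0679 for both MSH5 and FHIT at 3 h.

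edgeR called 75 genes at 0 h (62 higher, 13 lower), 55 at 1 h (41 and 14) and 58 at 3 h (47 and 11) of 21028 tested, and 18, 14 and 15 of them changed at least 2-fold. DESeq2 called 115, 115 and 103, and a fit on the 6 compared libraries alone called 34, 17 and 28. Without wild-type replicate 3 at 0 h, 48 genes were called there (39 higher), and 41 were higher without wild-type replicate 1. At 1 h 9 were lower without wild-type or mutant replicate 2, and at 3 h 6, 7 and 6 were lower without mutant replicates 1, 2 and 3. Of 72 genes higher at any time, 36 were higher at all 3 times, against 2.7e-04 for independent lists, and of 19 lower genes 8 were lower at all 3, against 4.5e-06. The 3 times share no libraries but share one estimate of the spread. The 36 genes had median log2 fold changes of 0.69 to 0.78, and the 8 lower genes, which include AT3G11100 and ASR3, of -0.88 to -0.82.

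**Figure D3:**
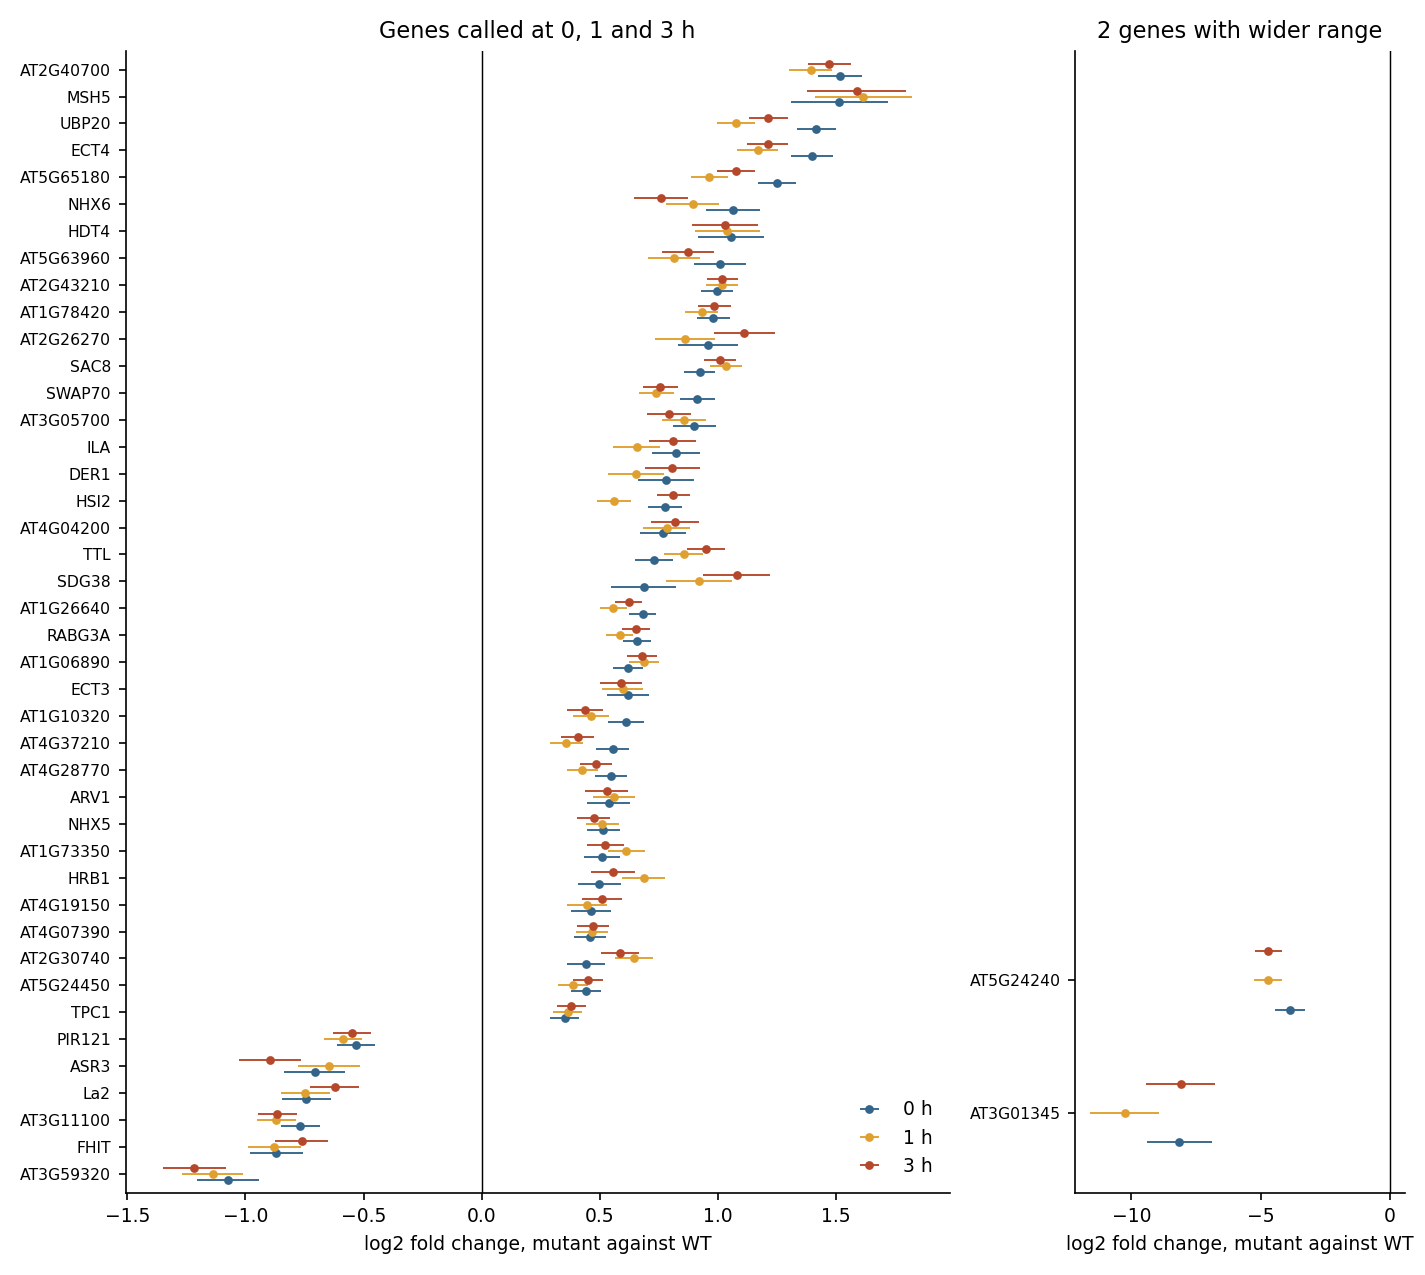
Genes called in the double mutant against the wild type at 0, 1 and 3 h, with the log2 fold change on the horizontal axis, bars of 1 SE and a colour per time; the right panel has a wider axis for AT3G01345 and AT5G24240. The 36 higher genes have medians between 0.69 and 0.78, and the 8 lower genes include AT3G11100 and ASR3.

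Defence gene lists were close to the wild type in the double mutant. No list member other than ASR3 and AT3G11100 was called at any single time, with medians of 0.03, -0.15 and 0.08 for early pattern-triggered genes and 0.03, -0.05 and -0.09 for salicylic acid genes at 0, 1 and 3 h. The genotype effect averaged over the times called a few more members, as given below. Camera called 5, 9 and 4 lists, and none held with an estimated correlation, where the lowest adjusted p was 0.255, 0.173 and 0.952. Fry called 0, 1 and 0 lists. Among the camera calls, those leaning lower included the abscisic acid, drought and cold list at 0 h (median -0.33, or -0.21 without a filter, adjusted p = 1.2e-04), the ethylene list at 1 h (median -0.16, adjusted p = 7.5e-04) and the jasmonate list at 3 h (median -0.25, adjusted p = 1.6e-04). Others leaning lower were trihelix, ethylene and clock genes at 0 h, trihelix, early pattern-triggered, jasmonate, clock and WRKY genes at 1 h, and abscisic acid and WRKY genes at 3 h, each lost without at least 1 library. The trihelix list includes ASR3 and AT3G11100, and it was not tested without them. The abscisic acid call was also lost without wild-type replicate 1 or mutant replicate 2 at 0 h (adjusted p = 0.346, median -0.09, and adjusted p = 0.0600), and the jasmonate call without wild-type replicate 1 at 3 h (adjusted p = 0.0739, median -0.16). The early pattern-triggered median at 1 h was 0.02 without mutant replicate 1, 0.05 without wild-type replicate 3, -0.28 without wild-type replicate 2 and -0.35 without mutant replicate 3. The ethylene median at 1 h was -0.25 without mutant replicate 3, and the jasmonate median at 3 h was -0.38 without wild-type replicate 3. In simulated counts for 0 h, 98.2% of 4-fold, 80.6% of 2-fold changes and 38.2% of log2 changes of 0.5 were recovered. Changed genes were above a minimum mean count and libraries were drawn independently. Recovery may therefore be lower for list members with few counts, such as WRKY30 (0.603 CPM in the wild type at 0 h).

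Lists leaning higher in the mutant were aliphatic glucosinolates at 0 and 1 h (medians 0.19 and 0.31, camera adjusted p = 0.0456 and 0.0122), photosynthesis at 1 and 3 h (0.20 and 0.18, adjusted p = 0.00192 and 7.0e-04) and flavonoids at 1 h (0.39, adjusted p = 0.0163). With an estimated correlation the adjusted p was 0.997 and 0.737 for aliphatic glucosinolates, 0.737 and 0.952 for photosynthesis and 0.301 for flavonoids. Aliphatic glucosinolates at 0 h lost the call without wild-type replicate 1 or 2 (adjusted p = 0.172, and 0.439 at a median of 0.09), mutant replicate 2 or 3 (0.378, and 0.404 at a median of 0.12), with library totals alone (0.0784) and without a filter (0.142), and had a median of 0.30 without mutant replicate 1. At 1 h they lost it without wild-type replicate 2 (0.393) or mutant replicate 3 (0.0709, median 0.18). Photosynthesis lost the call at 1 h without wild-type replicate 1 (0.276, median 0.08) and at 3 h without wild-type replicate 2 or 3 (0.275 at a median of 0.06, and 0.0717), and had a median of 0.39 at 3 h without wild-type replicate 1. Flavonoids lost it without any 1 of the 6 libraries: the adjusted p was 0.263, 0.226 and 0.111 without wild-type replicates 1, 2 and 3 (medians 0.21, 0.33 and 0.25), and 0.0711, 0.306 and 0.151 without mutant replicates 1, 2 and 3 (medians 0.26, 0.20 and 0.18).

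To compare overexpression leaves with the double mutant, where the ASR3 and AT3G11100 transcripts were lower but present, the genes called in OXAITF1 leaves were followed in mutant seedlings. The set higher in leaves (1689 of 1745 tested in seedlings) had medians of -0.06, -0.04 and -0.02 at 0, 1 and 3 h, and the set lower in leaves (1872 of 1947) had medians of 0.05, 0.12 and 0.09. Camera adjusted p was 5.1e-07, 1.8e-04 and 0.0494 for the first set and 5.8e-04, 2.0e-11 and 8.8e-07 for the second. With an estimated correlation the higher set at 0 h kept an adjusted p of 0.0303 and the other tests had an adjusted p of 0.0805 and 0.267 (higher set, 1 and 3 h) and of 0.385, 0.194 and 0.267 (lower set). The call of the higher set at 3 h was lost without wild-type replicate 1, 2 or 3 of that time (adjusted p = 0.0900, 0.0683 and 0.0941), mutant replicate 1 (0.357, median -0.0034) or 2 (0.106), or OXAITF1 replicate 1 (0.108), and its median was -0.043 without mutant replicate 3. The call of the lower set at 0 h was lost without wild-type replicate 2 (adjusted p = 0.582, median 0.012) or mutant replicate 3 (0.524, median 0.0030), and its median was 0.097 and 0.087 without replicate 1 of the wild type or the mutant. The lower set had medians of 0.070 and 0.078 at 1 h without wild-type replicate 1 or OXAITF1 replicate 1, and of 0.039 at 3 h without wild-type replicate 2. The higher set at 1 h had a median of -0.029 without wild-type replicate 2. The leaf-higher set and the mutant-lower genes shared 4, 5 and 4 genes at 0, 1 and 3 h, against 1.11, 1.203 and 0.925 for independent lists (Fisher's exact test, adjusted p = 0.0350, 0.00981 and 0.0194). AT3G11100 is among them, and without it, a test chosen after the overlaps were seen, 3, 4 and 3 remain against 1.02, 1.11 and 0.832, with only 1 h past the threshold (Fisher's exact test, adjusted p = 0.132, 0.0393 and 0.0816). In the same direction, the leaf-higher set and the mutant-higher genes shared 4, 4 and 5 genes against 5.36, 3.79 and 4.25 (Fisher's exact test, adjusted p = 1.00, 1.00 and 0.910), and the leaf-lower set and the mutant-lower genes 0, 1 and 1 against 1.23, 1.33 and 1.03 (0.910, 1.00 and 1.00). The leaf-lower set and the mutant-higher genes shared fewer: they shared 2, 0 and 2 genes against 5.95, 4.203 and 4.72 for independent lists (Fisher's exact test, adjusted p = 0.208, 0.0350 and 0.368), so at 1 h they shared fewer than independent lists give. These sets inherit the fragility of the leaf calls. Unadjusted p by Fisher's exact test was 0.0197, 0.00460 and 0.00971 for leaf-higher with mutant-lower genes. At 1 h it was 0.0197 without AT3G11100, and 0.0190 for leaf-lower with mutant-higher genes. The adjustment pools these tests with overlaps among seedling comparisons, whose p is far smaller. Over the leaf and mutant tests alone the adjusted p would be larger.

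To follow the response of wild-type seedlings over time, 1 h was compared with 0 h. Immune genes rose broadly. Of 36 early pattern-triggered genes 34 rose, with a median log2 fold change of 2.58: WRKY30, a transcription factor, went from 0.603 ± 0.294 to 88.7 ± 13.5 CPM and CYP81F2, an indole glucosinolate hydroxylase, from 7.02 ± 1.99 to 332 ± 102 CPM (SD, n = 3), while PHI-1, the phosphate-induced gene, fell by 3.25. In the camalexin and indole glucosinolate list 20 of 23 rose (median 3.16), with the methyltransferase IGMT2 at 6.52 (SE 0.30) and the sulfotransferase SOT16 at 3.87 (SE 0.27). Pattern receptors and signalling genes rose in 21 of 23 cases (median 1.22), with the chitin receptor CERK1 going from 39.3 ± 6.22 to 181 ± 40.3 CPM (SD, n = 3), the kinase MKK4 at 2.31 (SE 0.20) and MPK11 at 5.97 (SE 0.42). Of 24 cysteine-rich receptor kinases 20 rose and 3 fell (median 2.23), with CRK14 at 4.82 (SE 0.36).

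Heat shock genes rose in 11 of 12 cases, with a median of 5.11. HSP90.1, a chaperone, rose by 5.21 on the log2 scale (SE 0.48) and the regulator HSFA2 rose by 7.06 (SE 0.60). Of 28 photosynthesis genes 26 fell (median -0.92), LHCB4.2 from 515 ± 114 to 220 ± 22.3 CPM. The salicylic acid list had 14 higher members and 1 lower of 22 (median 0.99), with the transporter EDS5 at 2.55 and the immune regulators PAD4 and EDS1 at 1.63 and 1.24. The jasmonate list had 19 higher and 3 lower of 31 (median 0.92), with LOX4 at 5.54. Of 59 WRKY genes 37 rose and 5 fell (median 0.88), and 12 of 21 intracellular immune receptors rose and 1 fell (median 0.46), with RPM1 at 1.64. Camera adjusted p for these 10 lists lay between 9.7e-16 (early pattern-triggered) and 0.00849 (intracellular immune receptors), and none held with an estimated correlation, where the adjusted p was 0.215 to 0.467. Of all 23 lists tested, fry called 14. Adjusted over the list alone, 34 early pattern-triggered, 22 pattern receptor, 20 camalexin and 11 heat shock genes were higher and 26 photosynthesis genes lower.

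**Figure D4:**
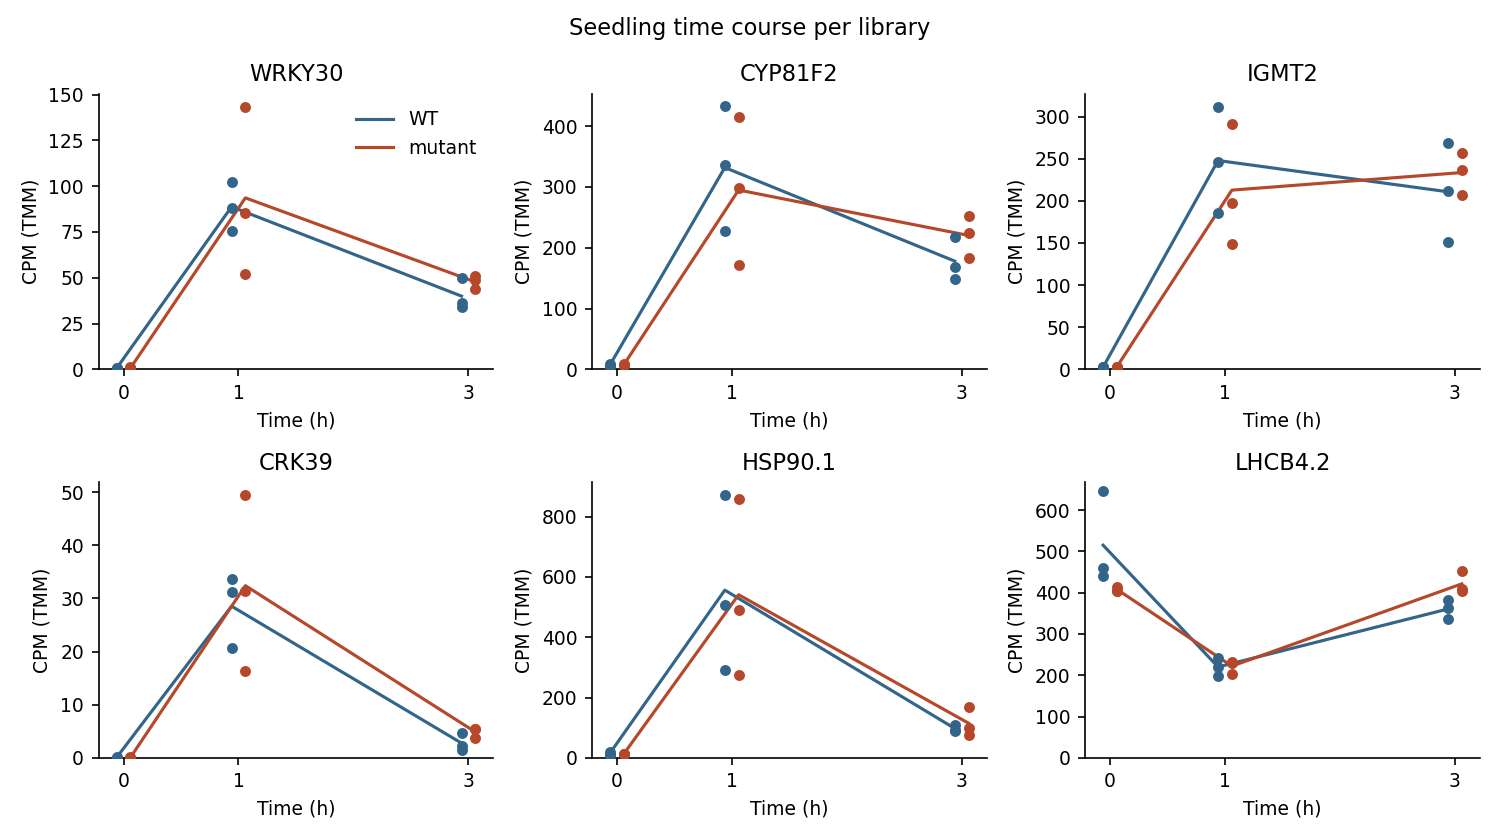
CPM (TMM-scaled, vertical axis) against time in hours for 6 genes in wild-type (blue) and double-mutant (red) seedlings, with 1 point per library and lines through group means of 3 libraries. WRKY30 averages 88.7 CPM in the wild type and 93.6 CPM in the mutant at 1 h, and LHCB4.2 averages 220 and 222 CPM.

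Other lists at 1 h had members in both directions or few calls and did not pass the list test. Counts higher and lower were 10 and 5 of 18 for ethylene, 7 and 8 of 26 for trihelix (GT-3B at 1.87, GTL1 at -0.99) and 5 and 6 of 20 for the clock. They were 2 and 4 of 19 for abscisic acid, 4 and 2 of 11 for touch (TCH3 at 1.84), 4 and 1 of 15 for auxin, 3 and 2 of 16 for aliphatic glucosinolates (SOT17 at 3.79) and 1 and 2 of 6 for flavonoids. Among markers of other cell types, 3 of 10 root genes rose, 4 of 8 guard cell genes and 1 of 5 phloem and trichome genes fell, and no edgeR call was made among 8 cell cycle genes. Of 6 reference genes UBQ10 rose by 0.53 and ACT2 fell by 0.26 (adjusted p = 0.0252 for ACT2, and 0.0664 or 0.0597 without wild-type replicate 1 or 3 at 0 h). CYP82C3, with 0 counts at 0 h, was at least 506-fold higher at 1 h against a floor of 3 counts over the group, and the phloem protein gene PP2-B13 at least 167-fold. The lowest called genes included SOB5 (-3.02, SE 0.45) and the cell expansion gene EXO, from 279 ± 46.6 to 45.3 ± 5.80 CPM (SD, n = 3). edgeR called 10142 of 21028 genes (5308 higher, 4834 lower), 2575 of them by at least 2-fold.

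At 3 h in the wild type, many of the same lists remained above 0 h. Early pattern-triggered genes were higher in 34 of 36 cases (median 1.97), camalexin and indole glucosinolate genes in 21 of 23 with 1 lower (median 2.13), with CYP71A12 rising from 0.256 ± 0.172 to 96.5 ± 18.7 CPM (SD, n = 3). In the salicylic acid list 14 of 22 rose (median 1.03), including EDS16, the isochorismate synthase, at 2.39 (SE 0.27) and the regulator SARD1 at 1.61 (SE 0.21). Of 31 jasmonate genes 17 rose (median 1.00, ORA59 at 2.78), of 24 cysteine-rich receptor kinases 18 (median 1.07, CRK13 at 3.70) and of 23 pattern receptors 16 (median 0.52, the co-receptor BAK1 at 0.91). Of 59 WRKY genes 32 rose and 2 fell (median 0.92, WRKY72 at 1.70). Of 18 ethylene genes 11 rose and 1 fell (ACS8 at 2.87), of 21 intracellular immune receptors 10 (ZAR1 at 0.89) and of 12 heat shock genes 8 (median 2.56; HSP90.1 at 2.69). Photosynthesis genes were lower in 17 of 28 cases (median -0.53). The touch list (4 of 11 higher) and the auxin list (5 of 15 higher and 1 lower; GH3.3 at 2.57) were the other calls.

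For these 13 lists camera adjusted p lay between 3.9e-25 and 0.0251, and none held with an estimated correlation, where the lowest adjusted p was 0.0567 and the highest 0.260. Of all 23 lists tested, fry called 16. The touch call was lost without wild-type replicate 2 at 0 h (adjusted p = 0.126) or replicate 1 or 2 at 3 h (adjusted p = 0.134 and 0.0516), and the auxin call without replicate 3 at 0 h or at 3 h (adjusted p = 0.0868 and 0.0779). The highest genes included the peptide precursor PROPEP3 (6.96, SE 0.66) and GSTU12 (6.86, SE 0.44), and the lowest CER4, a wax alcohol enzyme (-3.88, SE 0.59), and EXPB1, an expansin (-3.14, SE 0.45). edgeR called 5584 genes (3240 higher, 2344 lower; 1388 by at least 2-fold). The count was 3216 without wild-type replicate 2 at 3 h, 3365 without wild-type replicate 1 at 0 h, and 3293 in a fit of the 6 compared libraries, with 70.5% of calls higher in place of 58.0%. Lower genes numbered 1004, 1024 and 972 in these 3 fits, and 1460 without wild-type replicate 3 at 3 h.

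**Figure D5:**
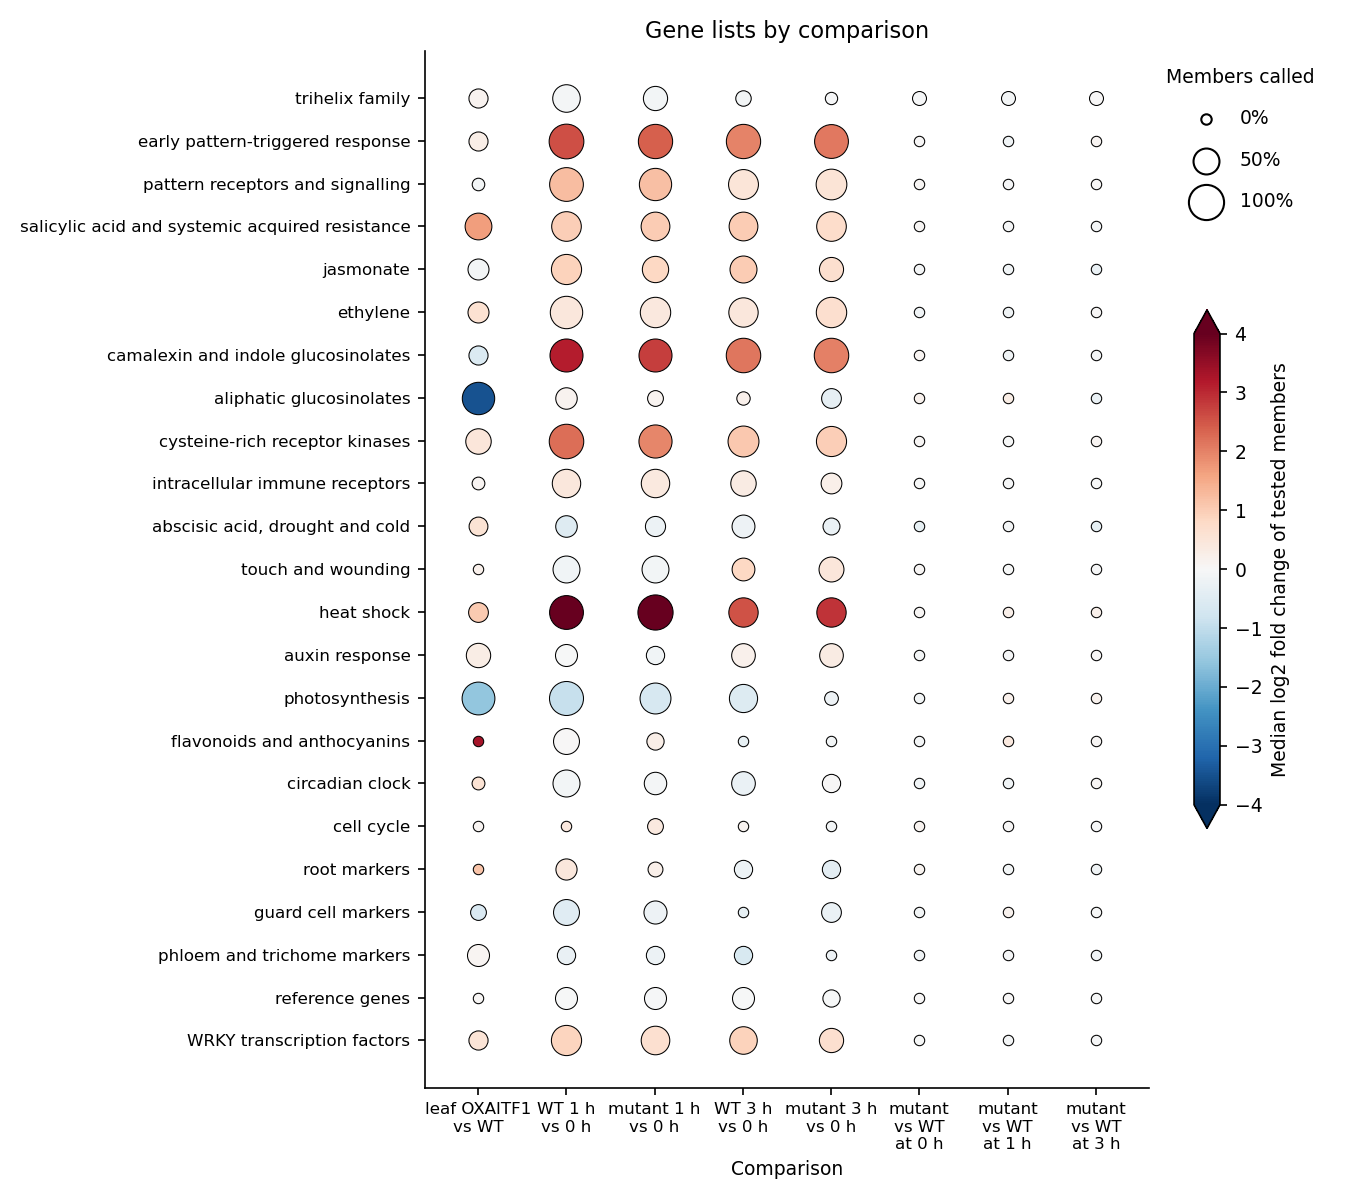
Median log2 fold change (colour, limited to 4 in either direction) and share of tested members called (dot size) for 23 gene lists (vertical axis) in 8 comparisons (horizontal axis). The photosynthesis list has medians of -1.57 in OXAITF1 leaves and -0.92 in wild-type seedlings at 1 h, and no list holds with an estimated correlation.

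Double-mutant seedlings went through a similar course. At 1 h, 33 of 36 early pattern-triggered genes rose (median 2.38; WRKY30 at 7.14), as did 20 of 23 camalexin and indole glucosinolate genes (median 2.78, or 2.47 with a gene at its lower bound). Also higher were 19 of 23 pattern receptors (median 1.21), 14 of 22 salicylic acid genes (median 1.02), 20 of 24 cysteine-rich receptor kinases with 1 lower (median 1.95) and 12 of 12 heat shock genes (median 5.20). Of 28 photosynthesis genes 21 fell (median -0.67). Camera called 10 lists and fry 13, with no call by camera at an estimated correlation (lowest adjusted p = 0.131). At 3 h, 33 of 36 early pattern-triggered genes were higher (median 2.12), 8 of 12 heat shock genes (median 2.89), 15 of 22 salicylic acid genes (median 0.74) and 12 of 18 ethylene genes with 1 lower (median 0.68), and 2 of 28 photosynthesis genes were lower (median -0.22). Of 10 root markers 2 were lower at 3 h (list adjusted p = 0.0300, and 0.491 with an estimated correlation; 0.103 without mutant replicate 2 at 0 h and 0.114 without mutant replicate 3 at 3 h; 0.0876 with library totals alone). Camera called 14 lists at 3 h (lowest adjusted p = 0.0653 with an estimated correlation) and fry 13.

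edgeR called 8312 genes in the mutant at 1 h (4270 higher, 4042 lower) and 4098 at 3 h (2783 higher, 1315 lower), and 2593 at 3 h without mutant replicate 3 of that time (599 lower). At 3 h 860 were lower without mutant replicate 3 of 0 h, and library totals alone gave 2276 higher and 2341 lower, or 49.3% higher in place of 67.9%. Of the genes called in both genotypes at 1 h, 3805 were higher in both and 3628 lower in both, against 1078 and 929 for independent lists, with 0 in opposite directions in edgeR calls. At 3 h these were 2252 and 842, against 429 and 147, with 1 opposite. Log2 fold changes of the genotypes, which share no libraries, correlated across 21028 genes with a Pearson r of 0.93 at 1 h and 0.86 at 3 h (Spearman rho 0.88 and 0.72), and genes are not independent replicates. To ask whether the response itself differed between genotypes, the genotype by time interaction was tested. edgeR called 0 genes at 1 h and 0 at 3 h, DESeq2 called 0 and 0, and 474 and 853 genes had an unadjusted p under 0.05 where chance gives 1051.4. ASR3 had interaction log2 values of 0.06 and -0.19 (SE 0.18 for both, adjusted p = 1.00 and 0.996). In simulated counts 9.55% of interactions of log2 0.5 at 1 h were recovered, 61.5% of 2-fold and 90.0% of 4-fold interactions. The simulated counts were drawn independently for each library. Since the real interactions gave fewer small p than chance, recovery in the real data may be lower.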

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

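The list tests of the genotype by time interaction were planned before the data were examined, and the counts of other splits of the samples follow a fixed procedure whose outcomes were read after the interaction counts were seen. A difference between genotypes in the response of a gene list marked 10 results. At 1 h the median interaction log2 values were -0.21 for camalexin and indole glucosinolates, 0.26 for photosynthesis, 0.41 for flavonoids and anthocyanins, -0.32 for root markers and 0.24 for guard cell markers. At 3 h they were -0.26 for jasmonate, -0.35 for aliphatic glucosinolates, 0.24 for photosynthesis, 0.20 for the circadian clock and -0.40 for root markers. Camera adjusted p lay between 1.4e-05 and 0.0372, and between 0.753 and 0.874 with an estimated correlation, with fry adjusted p between 0.906 and 0.911, so that none of the 10 held, and each of the 10 camera calls was lost without at least 1 library. Without 1 library the medians at 1 h ranged over -0.43 to 0.05 (camalexin and indole glucosinolates, highest without wild-type replicate 3 of 1 h), 0.12 to 0.36 (photosynthesis), 0.06 to 0.45 (flavonoids), -0.46 to 0.06 (root, highest without wild-type replicate 1 of 0 h) and 0.06 to 0.41 (guard cell). At 3 h they ranged over -0.35 to -0.10 (jasmonate), -0.68 to -0.19 (aliphatic glucosinolates), 0.08 to 0.49 (photosynthesis), 0.11 to 0.26 (clock) and -0.59 to -0.10 (root). Single genes gave 0 calls by edgeR at either time (474 and 853 at an unadjusted p under 0.05, and 0 and 0 by DESeq2). Of 25 drawn splits of the samples, 25 gave at least as many calls as the real 0 at 1 h and 25 at 3 h, which any split does beside a count of 0, so this count decides nothing. The highest other values were 112 calls at 1 h and 2 at 3 h. The split with 112 calls exchanges the genotype labels at 0 h alone, so it adds the genotype differences of 0 and 1 h in place of comparing them. No group has 4 to 10 samples, so no single library was tested against its group.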

How the results depend on the processing

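The genotype effect averaged over times, the overlap without AT3G11100 and the leaf sets without 1 seedling or OXAITF1 library were added after the data were seen, and the other alternatives were planned. Counts moved by over 1.5 times were, for the mutant against the wild type at 0, 1 and 3 h, 115, 115 and 103 by DESeq2, 34, 17 and 28 with the compared libraries only, and 18, 14 and 15 at 2-fold. At 2-fold the counts were 2575 and 1388 in the wild type and 1888 and 1261 in the mutant at 1 and 3 h. With the compared libraries only, 3293 genes were called in the wild type at 3 h. The averaged effect gave 521 by DESeq2. In leaves, library totals alone gave 6414 and a replicate block 0 by edgeR (6060 at an unadjusted p under 0.05, 4491 by DESeq2 without a block). List calls went from 81 of 230 by camera to 0 with an estimated correlation (lowest adjusted p 0.0567) and 65 by fry. Fry called 8 lists in leaves and 0, 1 and 0 in the mutant against the wild type at 0, 1 and 3 h. At 1 and 3 h it called 14 and 16 in the wild type, 13 and 13 in the mutant, and 0 and 0 for the interactions. With an estimated correlation the leaf-lower set (medians 0.054, 0.12 and 0.092) had adjusted p 0.385, 0.194 and 0.267, and the leaf-higher set 0.0805 at 1 h (-0.043) and 0.267 at 3 h (-0.019). Fisher's exact test for the lower set and mutant-higher genes reversed the direction, with fewer shared genes than the expected 5.95, 4.203 and 4.72: 2 at 0 h (adjusted p = 0.208), 0 at 1 h (0.0350) and 2 at 3 h (0.368). For the higher set without AT3G11100 it gave 3 at 0 h (0.132) and 3 at 3 h (0.0816). These adjusted p rest on the pooled family of 32 tests and would be larger over the leaf and mutant tests alone. The early pattern list in the mutant against the wild type at 1 h reversed without mutant 1 h replicate 1 (median 0.02, adjusted p = 0.67; range without 1 library -0.35 to 0.050). The cause was not tested. Without 1 library, counts ranged over 0 to 6164 (leaves), 48 to 63, 40 to 49 and 41 to 67 (mutant against wild type), 8077 to 9862 and 3216 to 6312 (wild type over time), 6779 to 7727 and 2593 to 3458 (mutant over time), 0 to 0 (both interactions, 0 by DESeq2) and 167 to 261 (averaged). Leaf-set medians without 1 seedling or OXAITF1 library (no set is left without a leaf wild-type library) ranged over -0.08 to -0.05, -0.06 to -0.03 and -0.043 to -0.0034 (higher set) and 0.0030 to 0.10, 0.07 to 0.16 and 0.04 to 0.13 (lower set). Of 358 named gene results, 358 kept direction and call with DESeq2, 355 with RLE, 352 with totals alone, 299 with a replicate block and 275 of 301 with the compared libraries only; without 1 library 1782 of 2038 did, and 0 reversed.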

Other observations

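The sequence word test and the senescence list were written before their results were seen, and the other tests of explanations here, the genotype effect averaged over times and the 3 patterns weighed were chosen only after the results were seen.

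Averaged over the 3 times, with 9 libraries per genotype, edgeR called 233 genes between the double mutant and the wild type (158 higher, 75 lower), 18 and 9 of them by at least 2-fold, and DESeq2 called 521. In the trihelix family 3 of 26 members were lower (ASR3, AT3G11100 and GT-3A, the last chosen after its values were seen). The camera adjusted p was 0.0225, or 0.205 with an estimated correlation, and the fry adjusted p was 0.00145. ASR3 is mutated in this line, so the lean of the list is in part built in. The list was not tested without ASR3 and AT3G11100. Abscisic acid, drought and cold genes (none called), jasmonate genes (2 lower) and ethylene genes (1 lower) each leaned lower with a camera adjusted p of 2.8e-04, and had an adjusted p of 0.467 with an estimated correlation. WRKY and clock genes leaned lower and photosynthesis genes higher (adjusted p = 0.0244, 0.0293 and 0.0225, and 0.686, 0.467 and 0.896 with an estimated correlation). Of 24 cysteine-rich receptor kinases 1 was called lower and of 6 flavonoid genes 1 higher (list camera adjusted p = 0.858 and 0.325). Of 60 drawn splits, 1 (the real one) gave as many calls, the highest other giving 36, so a random division of the libraries is an unlikely source of this count. The splits cannot address a batch or background difference that goes with genotype. AT3G01345 and AT5G24240, chosen after their values were seen, were the lowest of the genes that recur at all 3 times; AT3G01345 averaged 77.2 ± 62.5 CPM in the wild type and 0.150 CPM in the mutant (SD, n = 9), and AT5G24240 52.8 ± 33.8 and 2.23 CPM.

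Of genes higher in the double mutant at 0, 1 and 3 h there were 36, on 5 chromosomes. Linkage within 1 Mb of ASR3 or AT3G11100 is argued against, since 0 of the 36 lie there (1.61 expected). As AT3G11100 is not named as AITF1, windows anywhere were also counted, and no 2 windows of 2 Mb hold more than 8. The fullest 2 Mb window holds 5. It lies near ASR3 (start 14209982) on chromosome 2, from AT2G26270 (start 11183842) to SWAP70 (end 13146060). Within 4 Mb of either gene lie 9 of the 36 (5.9997 expected). Looser linkage to ASR3 therefore stays open for the genes on chromosome 2. Loci silent in one line are argued against, since 0 of the 36 average under 0.1 CPM in either genotype (lowest 1.67 CPM). A shared upstream sequence was not found (most enriched 6-base word ATTTGA, family-wise permutation p of 0.519 over 1000 random sets). Opposite regulation by overexpression predicts a fall in OXAITF1 leaves. There the set had a median log2 fold change of 0.18 (camera p = 0.126, and 0.218 with an estimated correlation), so no fall was seen. Of the 36, 4 were called higher and 0 lower. Of all 18639 genes tested in leaves 1745 were higher and 1947 lower, so the 4 are near the overall share. Direct repression by the 2 factors, and background differences between the lines, may each contribute and stay open.

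Lower photosynthesis and higher salicylic acid genes in OXAITF1 leaves were weighed next. The 10 most abundant genes as the source are argued against, since their changed share shifts all others by a log2 of at most 0.094 in any pair of leaf libraries. The list medians were -1.57 and 1.68. This bound covers those 10 genes only. TMM factors, 0.855 to 0.876 in the wild type and 1.12 to 1.19 in OXAITF1, move leaf values by more. A change of scaling moves all genes alike, so by itself it cannot lower 1 list and raise the other. A single divergent overexpression library is argued against by medians of -1.56 or lower and 1.62 or higher without either one (2.62 for salicylic acid without wild-type replicate 1). A difference in leaf age or senescence may contribute: senescence genes had a median log2 fold change of 1.06, with 6 of 14 tested members higher, among them SEN1 (16.9 to 929 CPM), SAG21 and NAP (fry p = 0.00957, camera p = 0.00789, and 0.106 with an estimated correlation). In edgeR 0 members were called lower, though some had negative values, such as WRKY53 (-0.71, adjusted p = 0.355) and GLN1;4 (-1.08, adjusted p = 0.0977). The list shares 3 members with other lists. The labels give the same age for both lines, and an effect of the overexpressed factor stays open beside it.

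Heat shock genes higher at 1 h were weighed last. A single divergent library is argued against, since the lowest median log2 fold change without 1 library was 4.63 in the wild type and 4.51 in the mutant. Handling or temperature between 0 and 1 h cannot be told apart from the treatment, because 0 untreated seedling libraries at 1 h are among those analysed. The unnamed treatment may also raise these genes.

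A candidate explanation for the values of AT3G11100 is that AT3G11100 is the overexpressed and mutated AITF1 locus. Of 22 trihelix genes tested in leaves, 1 other than ASR3 was at least 2-fold higher in OXAITF1 and lower in the double mutant at all 3 times, and 1 gene of any family met both conditions. These counts restate the values that raised the idea and so do not test it, and no label names the locus, so this remains a hypothesis.

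Other splits of the 6 libraries of each seedling comparison were counted. In each of 7 comparisons 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. Real counts and the highest of the other splits were 34 and 7, 17 and 0, and 28 and 1 for the mutant against the wild type at 0, 1 and 3 h, 8377 and 0 and 3293 and 0 for the wild type at 1 and 3 h, and 8087 and 0 and 4625 and 0 for the mutant.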
